A study of Homo sapiens with 4 samples.

How the data were processed

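Expression was measured in OVCAR-3, an established human ovarian carcinoma cell line, on 4 one-colour Affymetrix arrays. Per the labels, 2 arrays came from cells given a vector without the H1.3 insert and 2 from cells given H1.3, and the replicates are called biological. The titles of the H1.3 arrays add an (H) to H1.3, whose meaning is not given in the sources used here. Nothing in the labels says whether replicates came from separate transfections or clones, so the p-values measure the spread between these arrays, which may include culture or handling. RNA was taken with TRIzol and cleaned on RNeasy columns, per the labels' protocols.

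The authors deposited log2 values, 1 column per array and 33297 transcript clusters, given to 2 decimals. RMA and Affymetrix Expression Console are named in the submitters' processing notes, and their versions are not given in the sources used here. RMA as published subtracts background, equalises the distributions of the arrays and summarises several probes per transcript cluster; no probe intensity was used here, so background, saturation and single probes could not be examined. The series text names a human exon array, whereas the identifiers of the value table are those of a human gene array's annotation table, and all 21214 identifiers of that table occur among the values. Probe positions and the genome build are not given in the sources used here.

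Gene names came from the platform's annotation, updated through gene identifiers to the NCBI RefSeq table of assembly GRCh38.p14. Of the transcript clusters, 19460 had exactly 1 symbol, 1754 had several and 12083 were unnamed here. The gene identifier was found in the RefSeq table for 19429 of the single-symbol clusters, which stand for 18417 genes. The main test used the 21214 clusters with a symbol. A cluster with several symbols was counted but is not given to any one gene.

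The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, default settings, no covariate), as the arrays labelled H1.3 minus the vector-only arrays. Benjamini-Hochberg adjustment was applied over all clusters tested, with a threshold of 0.05. The fit had 2 residual degrees of freedom, and the moderation added 5.16 prior degrees of freedom. With 2 arrays per group, their number limits the precision: the median standard error of a log2 difference was 0.13. All p-values below are adjusted limma values unless another test is named.

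Gene lists covering histones, cell identity, growth, signalling, stress, metabolism and markers of other cell types, 35 in all, were fixed before the data were examined, as were the test of each comparison, the rule for naming genes and the alternatives, except the 1 named as added later. Of 1062 list memberships, 939 were measured. Each list was tested with limma's camera against the other genes with a preset inter-gene correlation of 0.01, using the single-symbol cluster of highest mean for each of 18417 genes, and adjusted over the lists. An estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. The genes named are all measured linker histone genes and H19, then the 12 largest rises and the 12 largest falls among single-symbol clusters that passed and whose groups did not overlap, then up to 4 passing members per list, or 2 members with the smallest p where a called list had none. A gene with several clusters is represented by the one of highest mean.

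Other alternatives changed the variance moderation, the scaling between arrays, the filter on dim clusters, the clusters tested and the threshold, added the replicate number as a term, or left out each array in turn. In a step chosen after seeing the data, runs of neighbouring genes were examined in the order of the RefSeq table, for 9302 genes with a mean level of at least 6.84, as the median log2 difference in windows of 31 genes set against 1000 random gene orders. Overlapping windows of one sign beyond the 95th percentile of the random orders were joined into stretches. Coordinates are not given, since the build behind the array annotation is not named.

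The steps were tested on simulated data for the comparison of 2 arrays against 2 over 21214 clusters, with the measured means and fitted variances. Of the changed clusters, 84% at a 2-fold change and 99% at a 4-fold change were called, with 9 false calls, and 0 calls were made when nothing was changed. The simulated clusters varied independently of each other, so these figures do not cover genes that move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.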

Results

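Transcript levels were compared between OVCAR-3 cells carrying a vector alone (2 arrays) and OVCAR-3 cells labelled as carrying the linker histone H1.3 (2 arrays). The series was designed to find transcript changes that follow H1.3 overexpression. The median log2 value per array lay between 6.21 and 6.27. Across the named transcript clusters, which are not independent replicates, Pearson's r was 0.993 within each group and 0.987 to 0.991 between groups.

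The gene encoding H1.3 itself, H1-3, was not higher in the arrays labelled H1.3. Its log2 level was 8.65 and 7.88 in the vector-only arrays and 7.47 and 7.69 in the arrays labelled H1.3, a difference of -0.69 ± 0.24 (SE) with an adjusted p of 0.319. The difference was -0.30 without vector-only replicate 1 and -1.07 without vector-only replicate 2. The level thus ran against the label, although without passing the test, and every direction below refers to the arrays labelled H1.3. Whether the probes of this transcript cluster lie in the sequence carried by the vector is not given in the sources used here.

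None of the 9 measured linker histone genes passed over all transcript clusters tested, and 1 did when adjusted over the list alone. H1-6, the testis-specific variant, was the member with the smallest p, at 0.69 ± 0.16 (SE) and an adjusted p of 0.131. Differences were 0.30 for H1-1, 0.02 for H1-2, 0.08 for H1-4, 0.18 for H1-5, 0.21 for H1-7, 0.05 for H1-8 and -0.16 for H1-10. Histone genes resemble each other in sequence, so signal on their probes may be shared. Without H1.3 replicate 1 the difference was 0.07 for H1-1, 0.08 for H1-5 and 0.06 for H1-7, and without H1.3 replicate 2 it was 0.54, 0.29 and 0.36. That of H1-10 was -0.09 without vector-only replicate 1. Those of H1-2 and H1-4 changed sign without vector-only replicate 2 (-0.14 and -0.06) or H1.3 replicate 1 (-0.05 and -0.21), as did that of H1-8 without H1.3 replicate 1 (-0.19).

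A large fall was measured on the transcript cluster annotated to both H19, an imprinted noncoding RNA, and the ribosomal protein gene RPS12. Its level was 10.96 and 10.09 in the vector-only arrays and 7.34 and 7.35 in the arrays labelled H1.3, a difference of -3.18 ± 0.26 (SE) with an adjusted p of 0.00956. The other cluster annotated to RPS12, shared with the small nucleolar RNA SNORA33, differed by -0.22 with an adjusted p of 0.584. Leaving out any 1 array ended the call, with differences from -3.62 to -2.75, and so did testing the unnamed transcript clusters as well, where the adjusted p was 0.107. Of the 39 imprinted genes measured on clusters of their own, 0 passed limma over all clusters, 1 passed when adjusted over the list alone, and the list's median difference was 0.02 with a camera adjusted p of 0.790.

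**Figure D1:**
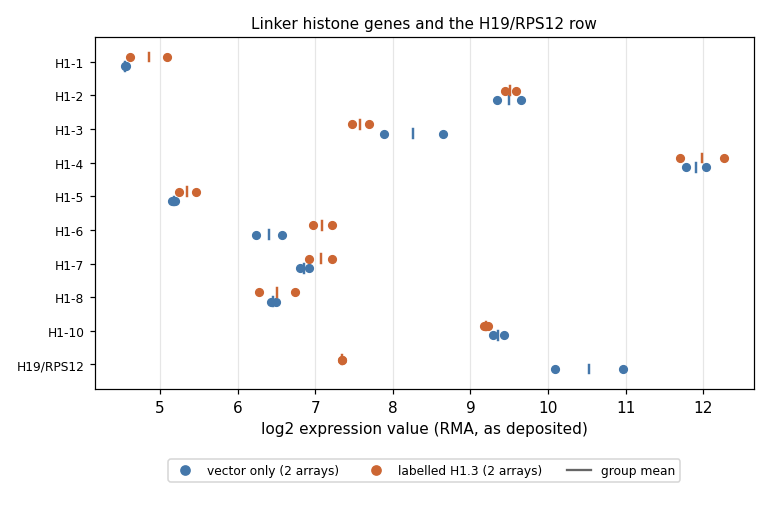
Log2 expression (horizontal axis) of the linker histone genes and of the transcript cluster annotated to H19 and RPS12, with 1 point per array, blue for vector only and orange for the arrays labelled H1.3, and bars at the group means. H1-3 lies at 7.88 and 8.65 in the vector-only arrays and at 7.47 and 7.69 in the others, while the H19/RPS12 cluster falls by 3.18.

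The strongest single change was a fall of H3C11, a replication-dependent histone H3 gene, from 9.32 ± 0.29 to 5.38 ± 0.13 (SD, n = 2 each), a difference of -3.94 ± 0.16 (SE) with an adjusted p of 0.000868. Among genes for secreted or surface proteins, NID2 (nidogen 2, a basement membrane protein) rose by 2.60 ± 0.17, GPNMB (a transmembrane glycoprotein) by 2.02 ± 0.25, and S100A8 (a calcium-binding subunit of calprotectin) by 2.62 ± 0.37. IL12A, the p35 subunit of interleukin 12, fell by 2.36 ± 0.14, PLIN2, a lipid droplet coat protein, by 2.18 ± 0.20, and the receptor tyrosine kinase gene ERBB4 by 2.00 ± 0.30 (SE throughout).

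Among the other large rises, CNTN1, a neuronal cell adhesion molecule, rose by 1.98, GRIA4, a glutamate receptor subunit, by 1.85, GABBR2, a GABA-B receptor subunit, by 1.76, and STXBP5, a syntaxin-binding protein, by 1.96. FLG, the epidermal protein filaggrin, rose by 1.78. The olfactory receptor gene OR7D2 rose by 2.03, the phosphatase gene PTPRR by 1.82, HLA-DPA1 by 1.64 and the peptide transporter gene SLC15A1 by 1.61. In the arrays labelled H1.3, CNTN1, GRIA4, OR7D2 and HLA-DPA1 still averaged 6.27, 6.575, 6.355 and 6.605. These levels lay below the median of the named clusters, 6.84 on each array, and those of the other rises just named lay above it. The other large falls were in THSD4 (-2.10), the selenium transport protein gene SELENOP (-1.97), the gap junction gene GJA1 (-1.89), DNAJC15 (-1.80), PRTFDC1 (-1.75), SMIM43 (-1.75), the NADPH oxidase gene NOX4 (-1.71) and the TRAIL decoy receptor gene TNFRSF10D (-1.70). Adjusted p for these genes lay between 0.000868 for H3C11 and 0.0477 for ERBB4.

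**Figure D2:**
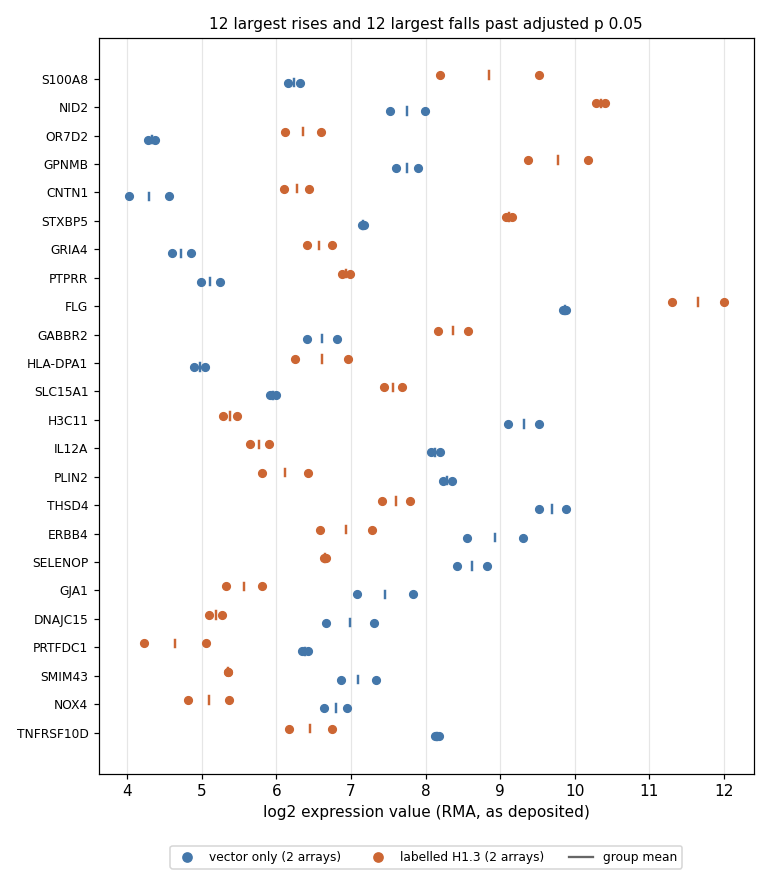
Log2 expression (horizontal axis) of the genes with the largest rises (upper part) and falls (lower part) that passed, with 1 point per array, blue for vector only and orange for the arrays labelled H1.3, and bars at the group means. The groups do not overlap for any gene shown, and the largest gap is that of H3C11, from 9.32 to 5.38.

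In all, 51 transcript clusters were higher and 56 lower in the arrays labelled H1.3 at an adjusted p under 0.05, of 21214 tested. They stand for 40 and 52 genes on single-symbol clusters. At least 2-fold changes made up 41 of the higher and 41 of the lower ones, and the smallest called difference was 0.82. The groups did not overlap for 40.6% of all clusters, against 33.3% by chance. Leaving out any 1 of the 4 arrays left 0 calls in limma, with 1292 to 2367 clusters at an unadjusted p under 0.05, and over the other refits the count of calls ran from 0 to 245.

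Of 43 measured interferon-stimulated genes, 39 had a positive difference and the median was 0.50, with a camera adjusted p of 1.18e-11 at the preset correlation and an adjusted p of 0.829 with an estimated correlation. None passed singly over all clusters, and 15 rose and 1 fell when adjusted over the list alone. TRIM22, an antiviral tripartite motif protein, differed by 1.04 ± 0.18 and HERC5, the ligase for ISG15, by 0.74 ± 0.13 (SE), both with an adjusted p of 0.0798. Without H1.3 replicate 2 the median of the list was 0.33.

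Antigen presentation genes had a median difference of 0.31 over 16 members, with a camera adjusted p of 4.06e-06 at the preset correlation and an adjusted p of 0.829 with an estimated correlation; fry gave 0.0274, and called only this list. HLA-DPA1 and HLA-DPB1, the chains of an MHC class II molecule, rose by 1.64 ± 0.22 and 1.00 ± 0.13 (SE), the other 14 did not pass, and 6 rose when adjusted over the list alone. Leukocyte markers, whose cells carry class II molecules, had a median difference of 0.07 over 17 genes. Of 32 inflammatory cytokines and NF-kB targets, the complement gene CFB rose by 1.38 ± 0.20 (SE) and 31 did not pass, while 11 rose and 1 fell when adjusted over the list alone. That list's median difference was 0.26, with a camera adjusted p of 1.28e-07 at the preset correlation and an adjusted p of 0.829 with an estimated correlation. It was 0.13 without H1.3 replicate 1, 0.40 without H1.3 replicate 2 and 0.66 without the clusters below the median level.

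Of 25 measured genes of cholesterol and fatty acid synthesis, 22 had a positive difference, and the median was 0.42. MSMO1, a sterol-C4-methyl oxidase of cholesterol synthesis, rose by 1.21 ± 0.17 (SE), the other 24 did not pass, and 12 genes rose and 1 fell when adjusted over the list alone. The camera adjusted p was 2.80e-10 at the preset correlation, with an adjusted p of 0.829 with an estimated correlation and of 0.559 with fry. Of the list's members, 32% lay in stretches of neighbouring genes that were shifted together, in either direction. MSMO1 was among them, with a median neighbour difference of 0.03. Of all genes placed, 12.3% lay in lower and 5.12% in higher stretches. The list's camera call at the preset correlation held without the genes of these stretches, an alternative chosen after seeing the data.

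Of 26 measured ovarian carcinoma markers, 17 had a negative difference and 24 did not pass. MECOM, a transcription factor gene, fell by 1.58 ± 0.18 and FOLR1, the folate receptor alpha gene, by 1.26 ± 0.15 (SE), and 7 fell when adjusted over the list alone. The median difference of the list was only -0.09, its mean was -0.34, and the camera adjusted p was 0.000547 at the preset correlation, with an adjusted p of 0.829 with an estimated correlation. Both genes lay in stretches of lower neighbours, with median neighbour differences of -0.20 for MECOM and -0.27 for FOLR1. The call was lost without the clusters below the median level (adjusted p 0.108), and the median was -0.15 without vector-only replicate 1, -0.18 without vector-only replicate 2 and -0.20 without H1.3 replicate 1.

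Of 44 measured cytoplasmic ribosomal protein genes, 42 had a negative difference, with a median of -0.17 and a camera adjusted p of 4.39e-07. For this list and the next 3, the adjusted p was 0.829 with an estimated correlation and 0.588 to 0.714 with fry. RPS25 differed by -0.61 and RPL10A by -0.55, with adjusted p of 0.188 and 0.237. The median was -0.11 over 45 genes of oxidative phosphorylation (camera adjusted p 0.000926), among them SDHD at -1.04 and COX8A at -0.54, and -0.23 over 29 genes of hypoxia and glycolysis (camera adjusted p 0.00524), among them the mitophagy receptor gene BNIP3L at -0.65 and the oxygen sensor gene EGLN3 at -0.58. Over 42 genes of DNA replication it was -0.09 (camera adjusted p 0.00524), with TYMS, thymidylate synthase, at -0.57 and FEN1, a flap endonuclease, at -0.36. Of these members, SDHD, RPS25, BNIP3L, COX8A, FEN1 and TYMS lay in stretches of lower neighbours, with median neighbour differences of -0.74, -0.48, -0.40, -0.32, -0.21 and -0.21. RPS25 differed by -0.39 without H1.3 replicate 1 and FEN1 by -0.22 without vector-only replicate 1.

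No member of these lower lists passed singly over all clusters; when adjusted over the list alone, 1 gene of oxidative phosphorylation fell and 0 in the others. The ribosomal protein call held without each array, with a median of -0.09 without H1.3 replicate 1. Without vector-only replicate 1 the calls for hypoxia and glycolysis (median 0.02), oxidative phosphorylation (-0.02) and DNA replication (-0.01) were lost, as were those for hypoxia and glycolysis (-0.05) and DNA replication (-0.08) without H1.3 replicate 2 and that for oxidative phosphorylation (-0.03) without H1.3 replicate 1. Without vector-only replicate 2 the medians were -0.39 for hypoxia and glycolysis, -0.24 for oxidative phosphorylation and -0.17 for DNA replication, and the alternative without the genes of shifted stretches, chosen after seeing the data, ended the calls for DNA replication (adjusted p 0.0628) and oxidative phosphorylation (adjusted p 0.0504). DNA replication also lost its call without the clusters below the median level (adjusted p 0.0537).

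Passing members of lists that were not called were COL5A2 and COL12A1, collagen genes that rose by 1.61 and 1.19, GSTP1, a glutathione transferase gene that fell by 1.00, and H3C11. Of the 40 core histone genes measured, H3C11 was thus the only one to pass, and the list's median was 0.03. The 26 lists without a call had medians from -0.08 to 0.14. Fibroblast markers had a median of 0.06 and endothelial markers of 0.02. The control list of housekeeping genes had a median of -0.08, near that of DNA replication, with 14 of 20 genes negative (camera adjusted p 0.153).

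**Figure D3:**
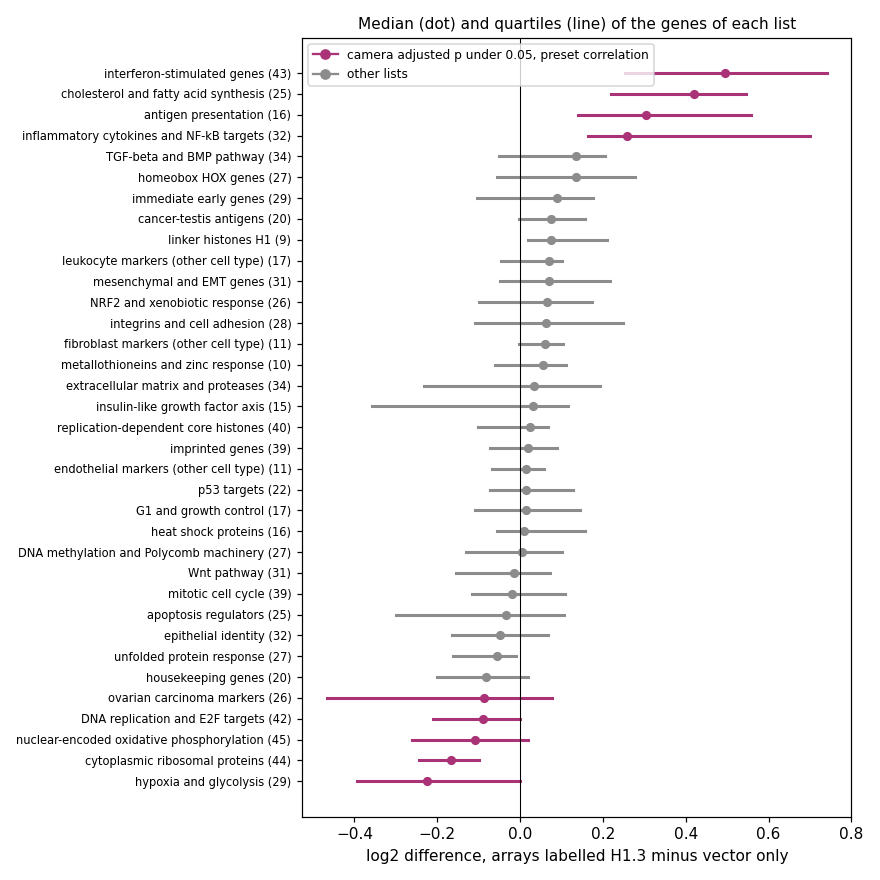
Median log2 difference (dots) and quartiles (lines) of the measured genes of each of the 35 lists, arrays labelled H1.3 minus vector only, with the number of genes in parentheses. Purple marks the 9 lists called by camera at the preset correlation, of which 4 lie above 0, up to a median of 0.50, and 5 below, down to -0.23.

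Neighbouring genes were also shifted together along parts of the genome. In windows of 31 expressed genes the largest absolute median difference was 0.72, against a 95th percentile of 0.21 over 1000 random gene orders, and the windows beyond it joined into 12 lower and 5 higher stretches. From PPFIA1 to ACAD8 the median of 186 genes was -0.46, and from FBXO25 to HOOK3 that of 106 genes was -0.42. NOX4 and FOLR1 lay in the former and TNFRSF10D in the latter, whereas GRIA4 rose within the former. IL12A lay in another, from EIF2A to MFN1, whose 45 genes had a median of only -0.05 and a strongest window of -0.40; the median over the nearest neighbours of IL12A was -0.67. Of 52 genes called lower, 28 lay in a lower stretch, as did 12.3% of all 18365 genes placed, and of 40 called higher, 7 lay in a higher stretch, as did 5.12%. Without the genes of these stretches, an alternative chosen after seeing the data, 18 transcript clusters were higher and 15 lower. Of the 107 clusters called in the main test, 69 were still tested, all with the same sign, and 33 passed. The drop thus also holds clusters outside the stretches that no longer passed in the refit.

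**Figure D4:**
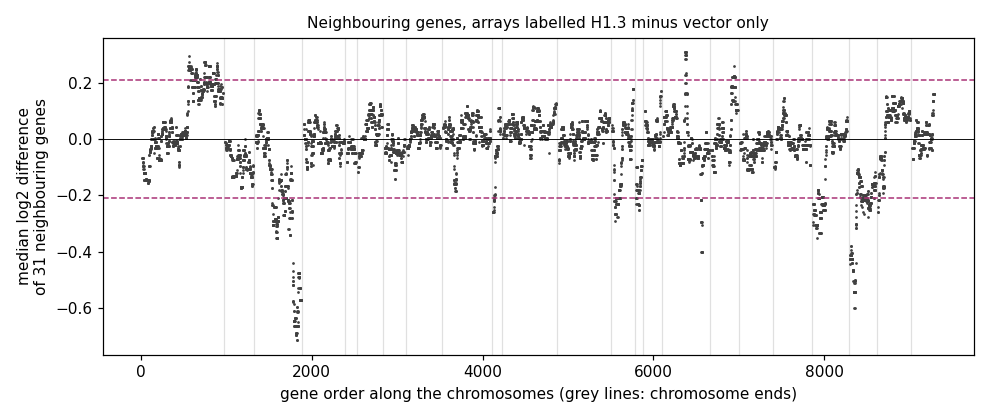
Median log2 difference of 31 neighbouring expressed genes (vertical axis) by gene order along the chromosomes (horizontal axis), arrays labelled H1.3 minus vector only, with grey lines at chromosome ends and dashed lines at plus and minus 0.21, the 95th percentile of random gene orders. Runs of windows leave this band in both directions, down to -0.72.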

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

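The fit without genes in shifted stretches was chosen after seeing the data; the other alternatives were fixed before. H1-3 stayed below 0 and uncalled in all refits, from -1.07 to -0.30 in the leave-one-out fits. In the main fit it was 1.61-fold lower at an unadjusted limma p of 0.0237, which meets the alternative threshold of 0.05 with at least 1.5-fold. Higher and lower transcript clusters (51 and 56) became 107 and 138 with a robust intensity trend, 29 and 38 after a second quantile normalization, 19 and 31 with arrays at one median, 6 and 19 without clusters below the median level, 1 and 3 with all transcript clusters, 18 and 15 without genes in shifted stretches, 135 and 176 at an adjusted p under 0.10, 282 and 401 at an unadjusted p under 0.05 with at least 1.5-fold, and 6 and 3 without moderation. Leaving out each array gave 0 to 0 for both counts, with a lone array assumed to vary like the other group. The cause of the shifts in the other settings was not tested. The H19/RPS12 cluster, at -3.18, lost its call with all transcript clusters (adjusted p 0.107), with the replicate block (0.117) and in the leave-one-out fits (-3.62 to -2.75). The lists called, 9 in the main test, were 0 with an estimated correlation (1 at an unadjusted p under 0.05), 1 with fry and 7 to 11 in all refits. The DNA replication list was lost in 4 of these, oxidative phosphorylation in 3, hypoxia and ovarian markers in 2 and 1. In leave-one-out fits H1-2 ran from -0.14 to 0.18, H1-4 from -0.21 to 0.36 and H1-8 from -0.19 to 0.28.

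With the replicate number as a replicate block, 0 transcript clusters were higher and 0 lower in limma (2195 at an unadjusted p under 0.05), and 9 lists were called. Replicate differences of the groups correlated at 0.06 and the labels state no shared batch, so the numbers were not taken to pair the arrays.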

Other observations

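The tests of exchanged arrays, exchanged labels and shared H1 probes, the split of the neighbour test by direction, the replicate ratios of single stretches, and the scan for stretches with the way its windows were joined were chosen after the results were seen; the other tests were written before their results were seen.

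The largest differences that did not pass were in TXNIP, a thioredoxin inhibitor, and THRSP, a lipogenic protein, both picked out after their values were seen. TXNIP measured 8.83 and 6.47 in the vector-only arrays against 11.28 and 10.84 in the arrays labelled H1.3, a difference of 3.41 with an adjusted p of 0.0913. THRSP measured 8.41 and 6.87 against 9.96 and 9.77, a difference of 2.23 with an adjusted p of 0.0922. Of the transcript clusters without a name here, 1 passed, lower in the arrays labelled H1.3, when all were tested.

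Of 15 measured genes of the insulin-like growth factor axis, 8 had a positive and 7 a negative difference, with a median of 0.03, and the list was not called (camera adjusted p 0.310). None passed over all clusters, and 4 fell when adjusted over the list alone. They were IGF1R at -0.53, IGFBP2 at -0.84, INSR at -0.46 and IGFBP3 at -0.57, with adjusted p over all clusters from 0.146 to 0.228.

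H1-3 was not higher in the arrays labelled H1.3. An exchange of 1 array of each group is argued against by the splits it would leave: at most 0 transcript clusters were called by limma when 1 array of each group was exchanged, against 107 by label, with 507 and 637 against 2450 at an unadjusted p under 0.05. Whether the labels were exchanged as a whole cannot be told apart here, since the adjusted p of H1-3 was 0.319. Signal of other H1 genes on the same probes may also hide a change: H1-3 lay 2.44 standard errors from H1-4 and 2.53 from H1-2, which neither excludes nor requires it. A transgene outside the reach of the probes stays open and was not tested.

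Of 34 transcript clusters annotated to MHC class II genes, 11 were called higher in the arrays labelled H1.3, among them clusters annotated to HLA-DRA and HLA-DQA1 together (differences of 2.17 to 3), and 23 did not pass, 5 of which differed by 0 or less, while HLA-DQA1 on its own cluster differed by 0.08, HLA-DQB1 by -0.20 and CIITA, the class II transactivator, by -0.02. Repeated clusters of 1 gene as the whole of the rise are argued against, since 2 different class II genes passed on clusters of their own. The counts of 11 and 34 still hold repeats. The 11 were annotated to HLA-DPA1, HLA-DPB1, HLA-DRA with HLA-DQA1, or a group of HLA-DRB genes with HLA-DQB1, each on repeated clusters. For HLA-DPA1, 2 clusters had the same level on every array (4.52 and 4.51 in vector only, 6.21 and 5.76 in the arrays labelled H1.3). Leukocytes among the cells are argued against by their markers, with a median difference of 0.07 (95% bootstrap interval over genes -0.05 to 0.10). Against the vector-only mean, that median was 0.165 in H1.3 replicate 1 and -0.045 in H1.3 replicate 2. PTPRC measured 3.38 and 3.40 and LYZ 3.84 and 3.67 in the arrays labelled H1.3. An interferon response may account for part of the rise, as a hypothesis. The interferon-stimulated genes had a median of 0.50 (0.41 to 0.64), with 0.325 in H1.3 replicate 1 and 0.62 in H1.3 replicate 2. Both intervals resample genes, so they do not measure the spread between arrays. The interferon list was called at the preset correlation, as this explanation required. That call was lost with an estimated correlation (adjusted p 0.829), and EPSTI1, another member, differed by -1.18.

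Stretches of neighbouring genes were shifted together, with the sign of the stretch in all 4 array pairs of each of the 17, which choosing them by the group difference favours. Copy number differences between the cell populations were examined through the neighbours of called genes, leaving out neighbours that were called themselves. As the main cause for the 40 genes called higher they are argued against, with a median signed neighbour difference of 0.0188 (bootstrap interval over genes -0.0175 to 0.0325). For the 52 called lower the cause stays open, at 0.16 (0.07 to 0.29). The median for all 92 was 0.0425 (0.0225 to 0.101), which by the prediction written beforehand argues against this cause. That median pools both directions, and it lies above the upper bound of 0.0238 for random genes. Neighbours were shifted with the called gene by at least 0.3 for 21.7% of all called genes and 36.5% of those called lower. Of all genes, 4.84% had neighbours shifted so far in either direction. By the bounds set, differences between single arrays stay open in 16 of the 17 stretches. In the strongest, from PPFIA1 to ACAD8, replicates differed by up to 0.16 against -0.46 between groups. Its median still ran from -0.58 to -0.355 over the 4 array pairs. From FBXO25 to HOOK3 replicates differed by 0.479 of the group difference (bootstrap interval widened for 17 stretches, 0.295 to 0.671). NDUFS3 to POLA2 had the lowest such ratio, 0.0755 (0 to 0.278), with -0.26 to -0.24 over the pairs. Differences between single arrays may account for the remaining stretch, from RPS20 to JRK, at 0.791 (0.512 to 1.06). These intervals resample genes, so they do not measure the spread between arrays. The spread of differences in the strongest stretch, from PPFIA1 to ACAD8, was 1.81 times that of other genes. It lay between the bounds set for a uniform shift of all genes and for a change in a part of them. The joined windows also differed in level, with a median of -0.12 around UVRAG and -0.715 around SDHD. A spread over such a mixture cannot tell these alternatives apart. Over the 17 stretches the ratio of spreads ran from 0.833, from EEF1D to SLC33A2, to 2.125, from EIF2A to MFN1. The bounds had been set for the strongest stretch only. The strongest stretch ran to ACAD8, the last scanned gene of chromosome 11. On chromosome 1, every window median was above 0 from TXNIP to the last window, at CEP170. Copy number thus could account for some stretches, but no DNA measurement was used here. An effect of H1.3 on these regions stays open and untested.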
